A study of Homo sapiens with 2 samples.

How the data were processed

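Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out in KYSE510, an established human esophageal squamous cell carcinoma line. Formaldehyde-fixed chromatin was sheared and precipitated with an antibody against MLL3 in 1 library and against GRHL2 in the other, per the labels' protocols. MLL3 (also called KMT2C) is a histone methyltransferase of enhancers, and GRHL2 is a Grainyhead-like transcription factor of epithelial cells. The design text also mentions cells with either factor silenced by siRNA, which were not analysed here. There was 1 library per antibody and no replicate, so no value below carries an error between replicates.

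For each antibody the authors deposited a narrowPeak list of regions called against an input control. BWA, Picard, MACS2 and deepTools and the genome build hg19 are named in the submitters' processing notes; versions and settings are not given in the sources used here. The fold enrichment, a ratio of the ChIP signal at the summit to the local background, and the −log10 p-value and −log10 q-value of each region are the authors' deposited values, and they describe each region within its own list. The score column of the deposited files was compared with the other columns. In the MLL3 list it was 10 times the −log10 q, truncated to a whole number, in 12195 of 12196 lines, and in the GRHL2 list it was 10 times the −log10 p in all 153209 lines. The lowest −log10 q in the MLL3 list was 2.07. The lowest −log10 p in the GRHL2 list was 1.30, and its lowest −log10 q was 0. The MLL3 list thus ends near a q of 0.01 and the GRHL2 list near an unadjusted p of 0.05, and the lengths of the lists are not comparable. The files give no read counts, so the sequencing depth is unknown, and an unequal depth could also change how many regions each list holds.

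Regions on chromosomes 1 to 22, X and Y were kept (12150 for MLL3 and 152864 for GRHL2). The 46 MLL3 and 345 GRHL2 lines on other contigs were left out of all comparisons. No interval was listed more than once, and no regions of one list overlapped each other. A region counted as shared when it overlapped a region of the other list by at least 1 bp. The overlap was set against 1000 random placements of the MLL3 regions, each on its own chromosome between the first and the last region of either list. This amounts to a one-sided permutation of positions, and p is the share of placements with as many overlaps, the real lists included, and its smallest possible value is 0.001. Random placement takes no account of open chromatin or of mappability. Medians of fold enrichment were compared within a list by a two-sided permutation test with 100000 resamples (smallest possible p 1e-05). Shares are given with exact Clopper-Pearson 95% intervals, which cover the counting of regions only and treat regions as independent. Regions are not replicates, so all p-values describe these 2 lists and not a spread between cultures. Coordinates are 1-based in hg19.

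The design, the tests and the first set of alternatives were fixed before the data were examined. Fixed alternatives were stricter thresholds (−log10 q of at least 2 or 5, fold of at least 5), an overlap of at least 50% of the shorter region, summits within 100 bp, a GRHL2 list reduced to the length of the MLL3 list, and a joint shift of all MLL3 regions of a chromosome. Alternatives added after seeing the data were a −log10 q of at least 2 in both lists for the comparisons, a move of each MLL3 region by 10 to 50 kb to either side, placement outside the longest empty stretch of each chromosome, and omission of 2 tracts with a high density of regions. The tract rule and the range of the move were each set once, after the density of the lists had been seen. Those tracts are runs of 1 Mb bins with at least 10 times the median number of MLL3 regions per occupied bin, which was 4.

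The rule for regions named in the text took the 10 highest by fold enrichment in each list and the 10 shared regions with the best product of ranks, at least 1 Mb away from the centromere. No gap annotation was used, and the longest stretch of a chromosome without a region of either list stood in for the centromere, which it is not on every chromosome. The parts of the rule that name genes were not applied. The only gene table at hand was in GRCh38 coordinates, and none of its positions were used. Assignment to genes, the 20 gene lists fixed beforehand, the distribution over promoters, exons and introns and the motif search, which need an hg19 annotation or sequence, were therefore not carried out.

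The overlap procedure was tested on simulated lists with the real widths. The GRHL2 regions were scattered at random over each chromosome, and those that ran into another were dropped. These lists therefore lack the clustering of the real ones, and the test checks the computation but not how well random placement suits clustered lists. With 60.0% of 12150 MLL3 regions planted on GRHL2 summits, 59.9% were recovered, and with none planted the overlap was 0.931 times that of the placements. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.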

Results

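Binding of MLL3 and GRHL2 was mapped by ChIP-seq in KYSE510 esophageal squamous carcinoma cells, with 1 library for each factor called against input. The study asked where these proteins, which its title describes as a complex, sit on chromatin. The MLL3 list held 12150 regions on chromosomes 1 to 22 and X, with a median width of 375 bp and a total of 5.33 Mb. The GRHL2 list held 152864 regions with a median width of 361 bp and a total of 74.3 Mb. No replicate exists for either factor, and the read depth is unknown.

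MLL3 regions were listed at a stricter threshold than GRHL2 regions, so the lengths of the lists are not comparable. Their median fold enrichment was 6.49 (quartiles 5.26 and 8.91, maximum 70.5), and all 12150 had a −log10 q above 2. GRHL2 regions reached a fold enrichment of 169, and most of the list was weak. Its median fold enrichment was 2.77 (quartiles 2.40 and 3.20), 105267 of its regions (68.9%) had a q above 0.05, and 41184 had the smallest width in the list, 265 bp. At a −log10 q of at least 2, which every MLL3 region passed, 30080 GRHL2 regions were left, and at a −log10 q of at least 5 the lists held 9720 MLL3 and 14248 GRHL2 regions.

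MLL3 regions mostly coincided with GRHL2 regions, on each of chromosomes 1 to 22 and X. Of the 12150 MLL3 regions, 10327 (85.0%, 95% interval 84.3 to 85.6%) overlapped a GRHL2 region, against 5.41% ± 0.209 (SD over 1000 random placements), a 15.7-fold excess (one-sided, by random permutation of positions, p = 0.001, the smallest the placements can give). When all MLL3 regions of a chromosome were shifted together, which keeps their clustering, the mean was the same 5.41% with a wider SD of 1.22. By chromosome, the share ran from 72.4% on chromosome X and 77.2% on chromosome 4 to 88.9% on chromosome 1 and 93.2% on chromosome 9. Without the 2 dense tracts described further on, chromosomes 1 and 9 had shares of 85.9% and 84.6%, and the highest were 88.5% on chromosome 21 and 88.4% on chromosome 10. Seen from the other list, 9404 of the 152864 GRHL2 regions (6.15%, 95% interval 6.03 to 6.27%) overlapped an MLL3 region, 14.0 times the mean of the placements (one-sided permutation of positions, p = 0.001). With both lists at a −log10 q of at least 2, 68.7% of MLL3 regions overlapped a GRHL2 region, 42.0 times the mean of the placements. With the GRHL2 list reduced to the 12150 regions of lowest q, the share was 46.4%, a 59.4-fold excess. The excess was smallest, 4.11-fold, when each MLL3 region was moved by only 10 to 50 kb (20.7% of moved regions overlapped), and without the tracts the same move gave 83.4% in place against 9.79%, an 8.52-fold excess.

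The strongest MLL3 regions were nearly all GRHL2 regions as well. Outside the dense tracts, 98.4% of the 1058 MLL3 regions with the highest fold enrichment (14.1 and above) overlapped a GRHL2 region (95% interval 97.4 to 99.1%), as did 72.1% of the 1057 with the lowest (4.55 and below, 95% interval 69.3 to 74.8%). The shares that met a GRHL2 region with a −log10 q of at least 2 were 91.6% and 51.1%. Over the whole MLL3 list, the median fold enrichment was 6.65 in the 10327 shared regions and 5.76 in the 1823 MLL3-only regions, a difference of 0.886 (permutation test, two-sided, p = 1e-05, the smallest possible). Outside the tracts that difference was 1.33 (7.09 against 5.76, permutation p = 1e-05).

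**Figure D1:**
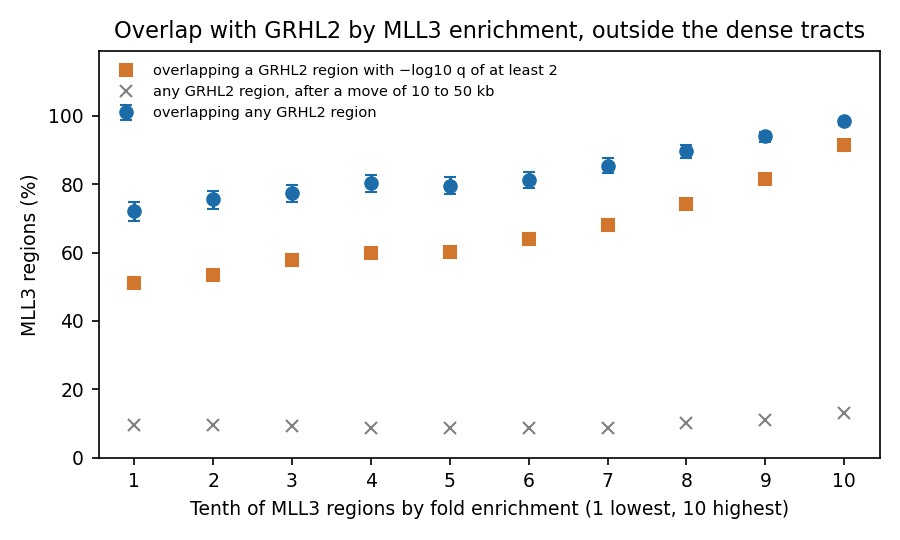
Percentage of MLL3 regions (vertical axis) that overlapped a GRHL2 region, in 10 equal groups of the MLL3 list by fold enrichment (horizontal axis, lowest to highest), outside the dense tracts. Circles with exact 95% intervals count any GRHL2 region, squares those with a −log10 q of at least 2, and crosses MLL3 regions moved by 10 to 50 kb; the circles go from 72.1% in the lowest group to 98.4% in the highest, and the crosses stay at or below 13.2%.

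The share of GRHL2 regions that carried MLL3 rose with their significance. Outside the dense tracts, an MLL3 region lay on 1617 of 2130 GRHL2 regions (75.9%, 95% interval 74.0 to 77.7%) with a −log10 q of at least 100, on 37.8% of 3898 regions between 20 and 100, on 25.4% of 7753 regions between 5 and 20, and on 11.6% of 14577 regions between 2 and 5. Among the 104056 GRHL2 regions with a q above 0.05 1250 were shared (95% interval of the share 1.14 to 1.27%). MLL3 regions moved by 10 to 50 kb met 2.35% of the strongest class and 0.561% of the weakest. In the whole list, shared GRHL2 regions had a median fold enrichment of 5.39 and a median width of 907 bp, against 2.69 and 349 bp for the 143460 GRHL2-only regions (difference in fold 2.70, permutation test, two-sided, p = 1e-05, the smallest possible). Wider regions also have more chance to overlap. The shares after moves take this into account, but the test of medians does not. Across the 8817 shared regions outside the tracts, the fold enrichments of both factors were positively related (Pearson r = 0.36 on log2 values, Spearman rho = 0.30, permutation p = 1e-05 for each), a relation across regions of 1 pair of libraries and not across samples.

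**Figure D2:**
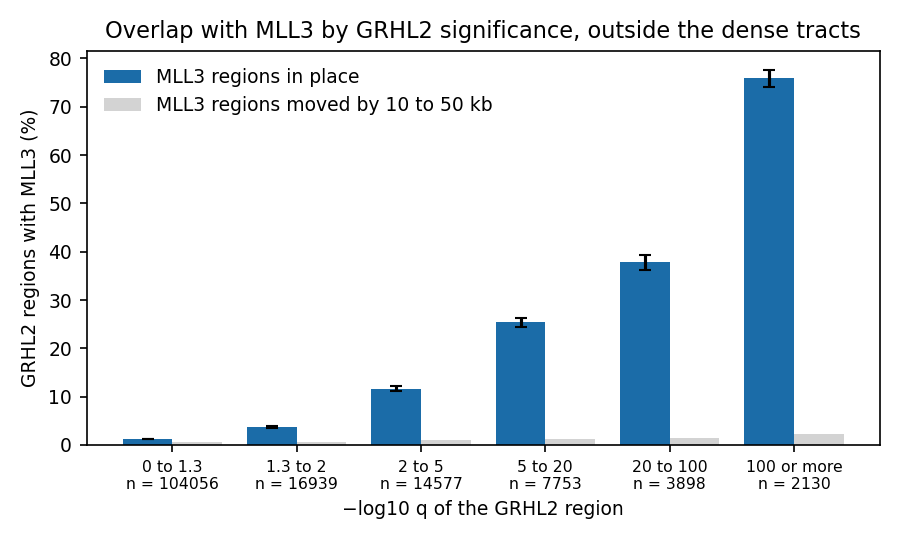
Percentage of GRHL2 regions (vertical axis) that overlapped an MLL3 region, by class of the GRHL2 region's −log10 q (horizontal axis, with the number of regions), outside the dense tracts. Dark bars with exact 95% intervals show MLL3 regions in place and pale bars the mean after moves of 10 to 50 kb; the dark bars rise to 75.9% in the strongest class, and the pale bars stay at or below 2.35%.

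Summits of shared regions lay within 100 bp of each other more often than those of displaced regions. The median distance from an MLL3 summit to the nearest GRHL2 summit was 104 bp over the 10327 shared regions, and 49.1% (95% interval 48.1 to 50.04%) were within 100 bp. In random placements that overlapped a GRHL2 region the mean median was 236 bp ± 10.3 (SD over 1000 placements), and 21.7% ± 1.57 were within 100 bp, with 26.8% in the highest placement. Outside the dense tracts the median was 85 bp, against 227 bp ± 10.6 in 200 placements of those regions, 33.1% of shared regions had summits within 50 bp, and 55.5% within 100 bp. Inside the tracts the median over 1510 shared regions was 859 bp, and 11.5% (95% interval 9.96 to 13.2%) were within 100 bp. After moves by 10 to 50 kb the tract regions that overlapped had a mean median of 841 bp ± 31.5 and 7.71% ± 0.678 within 100 bp (SD over 1000 moves, highest 9.91%, one-sided permutation of positions for the share within 100 bp, p = 0.001). Of all MLL3 regions, 41.7% had a GRHL2 summit within 100 bp of their own.

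**Figure D3:**
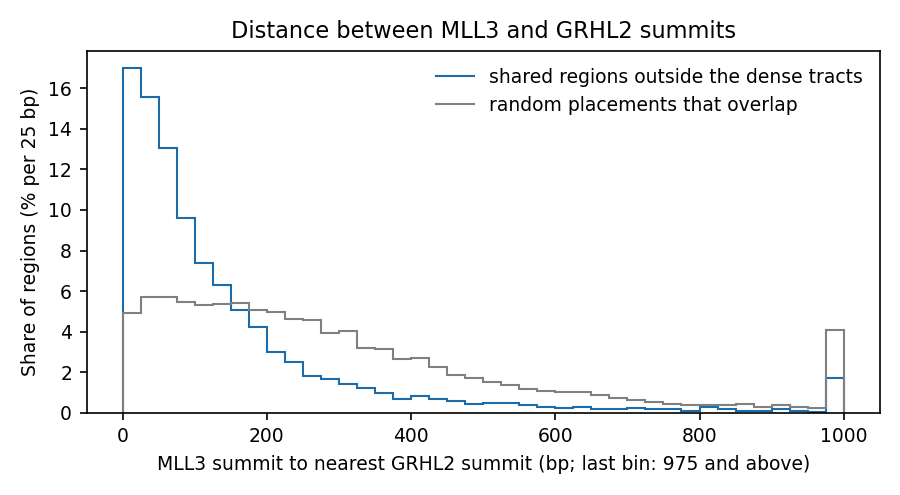
Share of regions per 25 bp (vertical axis) by distance from the MLL3 summit to the nearest GRHL2 summit (horizontal axis, bp). The line for shared regions outside the dense tracts is highest at 0 to 25 bp, where it holds 17.0% of regions, against 4.92% for genome-wide random placements that overlap a GRHL2 region.

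MLL3 regions were concentrated in tracts on chromosomes 1 and 9. The tract on chromosome 1 (212000001 to 216000000) held 712 MLL3 regions, 178 per Mb, and the tract on chromosome 9 (5000001 to 8000000) held 862, 287 per Mb. The rest of the genome had 3.55 per Mb. Both tracts together made up 7 Mb and 13.0% of the MLL3 list. GRHL2 regions covered 65.1% of the tract on chromosome 1 and 71.6% of that on chromosome 9, against 2.33% elsewhere, and 95.9% (95% interval 94.8 to 96.9%) of the 1574 MLL3 regions in the tracts were shared. After moves by 10 to 50 kb 93.9% ± 0.537 of them still overlapped a GRHL2 region (SD over 1000 moves, highest 95.3%, one-sided permutation of positions, p = 0.001). With so much of the tracts covered by GRHL2 regions, overlap there leaves little room for an excess over moved regions. The bounds follow MLL3: dense GRHL2 coverage went on beyond them. In covered length its largest fall on chromosome 9 was at 9400000. The mean there was 57.2% over the 5 bins of 100 kb before and 5.10% over the 5 after. By ratio of covered length the largest step on chromosome 9 was at 9600000. On chromosome 1 the largest fall in covered length was at 216700000, from 57.8% to 21.4%. Values outside the tracts still include these flanks. Outside the tracts, 83.4% of 10576 MLL3 regions were shared. Without the tracts, the densities of chromosomes 1 and 9 went from 6.54 and 10.0 MLL3 regions per Mb to 3.68 and 3.88, within the range of the other autosomes and X, of which chromosome 20 had the most (5.87) and chromosome X the fewest (1.67). The complete GRHL2 list was densest on chromosome 11 (94.2 regions per Mb), followed by chromosomes 5 (85.2) and 7 (77.5), but the order was different at a −log10 q of at least 2. Then chromosomes 9 (17.1 per Mb) and 1 (15.2) came first, with 13.8 on chromosome 11 and 11.4 on each of chromosomes 5 and 7, and without the tracts chromosomes 9 and 1 had 12.0 and 11.2 per Mb and chromosome 15 the most (14.4).

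**Figure D4:**
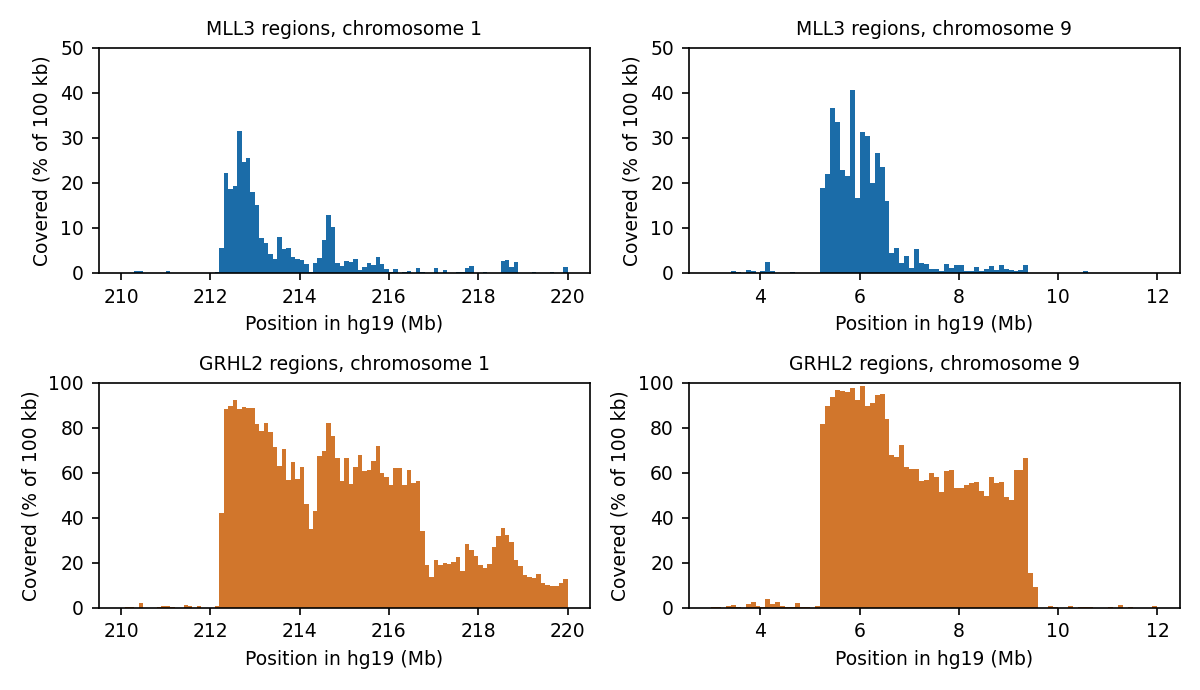
Percentage of each 100 kb bin covered by MLL3 regions (top, axis to 50%) and GRHL2 regions (bottom, axis to 100%) by position in hg19 (Mb), around the tracts on chromosomes 1 (left) and 9 (right). Coverage is near 0 before 212 Mb on chromosome 1 and 5.2 Mb on chromosome 9 and then steps up in both lists.

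The most enriched single regions of each factor were shared. All 10 MLL3 regions of highest fold enrichment (45.6 to 70.5) and all 10 GRHL2 regions of highest fold enrichment (151 to 169) overlapped the other list, and 3 of these MLL3 and 1 of these GRHL2 regions lay in the dense tracts. The top MLL3 region lay on chromosome 2 (99051779 to 99052854, fold 70.5) inside a GRHL2 region of fold 160, with 10 bp between the summits, and it was also first by product of ranks. The next by product of ranks were on chromosome 1 (215756553 to 215757577, MLL3 fold 65.2, GRHL2 fold 128, summits 9 bp apart, inside the dense tract), on chromosome 21 (39606282 to 39607619, MLL3 fold 44.0, GRHL2 fold 161, summits 9 bp apart) and again on chromosome 21 (44375580 to 44376598, MLL3 fold 36.8, GRHL2 fold 163, summits 20 bp apart). The MLL3 region of the third highest fold was in the tract on chromosome 1 (212768787 to 212770478, fold 56.0), with a GRHL2 fold of only 11.2. The tract on chromosome 9 held the last of the 10 (5879062 to 5880706, MLL3 fold 45.6, GRHL2 fold 39.6). The others of the 10 were on chromosome 1 (162883009 to 162884023, fold 53.0), chromosome 7 (49054260 to 49054975, fold 50.2), chromosome 8 (107620467 to 107621401, fold 49.1, and 96078412 to 96080157, fold 48.3), chromosome 11 (35643493 to 35644230, fold 47.4) and chromosome 12 (127609997 to 127611298, fold 46.8). The highest GRHL2 regions were on chromosome 2 (101943329 to 101945659, fold 169) and chromosome 9 (71734379 to 71738221, fold 169), where MLL3 had folds of 25.4 and 27.7. Overlap did not always bring the summits together: in the tract on chromosome 9 a GRHL2 region of 7778 bp (5444968 to 5452745, fold 159), among the 10 highest, held an MLL3 region (5446362 to 5447729, fold 35.4) whose summit was 3753 bp from its own. Of the 1000 GRHL2 regions of highest fold, 87.8% (95% interval 85.6 to 89.8%) were shared, as were 98.7% (97.8 to 99.3%) of the 1000 highest MLL3 regions. The genes nearest to these regions are not named, because no hg19 annotation was used here.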

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

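Regions on contigs outside the assembled chromosomes took no part in the comparisons. On 4 of the 26 such contigs with a region, both lists held more than 3 regions, a cut-off for listing them and not a test. The contig chrUn_gl000220 held 18 MLL3 and 64 GRHL2 regions, with folds up to 27.2 and 92.4. The contig chr7_gl000195_random held 8 MLL3 and 75 GRHL2 regions. The contig chr17_gl000205_random held 6 MLL3 and 55 GRHL2 regions. The contig chrUn_gl000224 held 5 MLL3 and 20 GRHL2 regions. No control library was analysed here to set these counts against, and no explanation was tested.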

How the results depend on the processing

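Of 32 alternative settings, 29 kept the direction, the side of the threshold or a count within 1.5 times the reported one. Of these, 3 could not change, since every MLL3 region passes a −log10 q of 2 and no interval is repeated in either list. The others were counts of GRHL2 regions, which went from 152864 to 30080 at a −log10 q of at least 2, to 14248 at a −log10 q of at least 5 and to 12946 at a fold of at least 5. The settings without the dense tracts, with regions moved by 10 to 50 kb, with placement outside the longest empty stretch and with both lists at a −log10 q of at least 2 for the overlap, summit distance and enrichment were chosen after seeing the data. The overlap of MLL3 with GRHL2 stayed above every random placement in all 12 of its alternatives, but its size depended on the setting, between 41.7% (summits within 100 bp) and 85.0% of MLL3 regions and between 4.11 (regions moved by 10 to 50 kb) and 61.1 times the placements (both lists at a fold of at least 5). The difference in enrichment between shared and unshared regions kept its sign in all 8 of its alternatives. The thresholds of the lists were unequal, and 1292 MLL3 regions (10.6%) met only GRHL2 regions with a q above 0.05. Read depth, which the files do not give, limits both lists to an unknown degree. Placement at a matched distance from transcription start sites, omission of repeats, and all settings of the genomic distribution, gene lists and motifs were not run for lack of an hg19 annotation and sequence. No paired analysis was possible because each antibody had 1 library.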

Other observations

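The tracts and the move by 10 to 50 kb were chosen after the lists had been seen, and so were all 4 tests of the crowding into the tracts, the test of summits within them and the test of the weak GRHL2 regions.

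Some GRHL2 regions carried several MLL3 regions. This was so for 550 of the 9404 shared GRHL2 regions, with up to 20 MLL3 regions in 1 of them, and 296 of the 550 lay in the dense tracts. Outside the tracts 254 GRHL2 regions (2.94% of those shared) had 2 or more, with a maximum of 3. The widest GRHL2 regions were on chromosome 9 (6022534 to 6051970, 29437 bp, and 6071379 to 6098588, 27210 bp), whereas the widest outside the tracts was 6949 bp. Some strong regions were listed for only 1 factor, and the following were chosen after their values were seen. Absence from a list is not absence of the factor, since each list has a threshold and the read depth is unknown. GRHL2 reached a fold of 149 on chromosome 1 (33365995 to 33368686) and of 146 on chromosome 19 (33495069 to 33498604) with no MLL3 region. MLL3 reached a fold of 34.2 on chromosome 11 (5246135 to 5247355) and of 19.9 on chromosome 19 (43324288 to 43324830) with no GRHL2 region.

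The crowding of both lists into the tracts on chromosomes 1 and 9 was weighed against 3 explanations. Stronger sites as its cause are argued against only for the typical MLL3 region. The median MLL3 fold was lower inside the tracts than outside (5.32 against 6.78, difference -1.46, permutation p = 1e-05), although 3 of the 10 highest MLL3 regions lay there. This median cannot exclude additional strong sites among many weak ones. Of the 5183 MLL3 regions with a −log10 q of at least 10, 2.62% lay in the tracts. The tracts spanned 7 Mb, against 2982 Mb for the rest of the genome. The GRHL2 median was higher inside (3.32 against 2.75, difference 0.565, permutation p = 1e-05), but it depends on the loose threshold of that list. Of the 105267 GRHL2 regions with a q above 0.05, 104056 lay outside the tracts. So did 16939 of 17517 with a q between 0.01 and 0.05 and 14577 of 15832 with a −log10 q between 2 and 5. The same held for 7753 of 8161 between 5 and 20, 3898 of 3935 between 20 and 100 and 2130 of 2152 with at least 100. Set against their 7 Mb, the tracts thus held more GRHL2 regions of every class per Mb than the rest of the genome. Strong and weak GRHL2 regions were both denser there, so the GRHL2 median cannot decide. Regions near the threshold of the peak caller may contribute to the MLL3 crowding, because the tracts held 13.0% of all MLL3 regions but 2.62% of the 5183 with a −log10 q of at least 10. A segment with extra copies that the input does not fully offset stays open. By ratio of covered length, the lists rose close together on the left, at 212200000 for MLL3 and 212100000 for GRHL2 on chromosome 1. On chromosome 9 both rose at 5200000, although the largest GRHL2 step there was on the right, at 9600000. The tracts were chosen for their MLL3 density, which makes a rise of MLL3 probable. On the right the largest falls in covered length were 3600 kb apart on chromosome 1 and 2900 kb apart on chromosome 9. GRHL2 coverage also fell where MLL3 coverage fell most (means of 5 bins of 100 kb). It went from 87.3% to 74.5% at 213100000 on chromosome 1 and from 93.7% to 70.7% at 6500000 on chromosome 9. Where GRHL2 fell most, MLL3 coverage was already low. On chromosome 9 it went from 1.69% to 0 between neighbouring bins. On chromosome 1 the neighbouring bins held 1.08% and 0.236%. Bins of 0 lay on both sides there, and a bin after the GRHL2 fall held 1.14%, so MLL3 showed no clear fall. The unequal thresholds of the lists may also set the falls apart, so their distance decides nothing. Copy number and input coverage were not analysed here, and no biological explanation was tested.

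For the overlap of MLL3 with GRHL2 regions, crowding of both lists into the same parts of the genome was weighed first. For the list as a whole, such crowding on scales of 10 kb or more is argued against. After a move by 10 to 50 kb 20.7% of MLL3 regions overlapped, against 85.0% in place. Moves of this length cannot test crowding within shorter distances. Inside the tracts overlap says little, since 95.9% overlapped in place and 93.9% still did after the move (highest 95.3%). Crowding with no shared sites is argued against there only by the share of shared tract regions with summits within 100 bp, 11.5% against at most 9.91% after moves. The median summit distance was no shorter in place (859 bp) than after moves (841 bp ± 31.5). How much of the tract overlap comes from crowding stays open. The dense tracts as the source of the overlap are argued against, since 83.4% of MLL3 regions outside them were shared. Open chromatin recovered by any antibody cannot be told apart from joint binding, because no library with an unrelated antibody was analysed here and either would give the positive relation between the enrichments (Spearman rho 0.296 outside the tracts). No biological explanation was tested.

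The weak part of the GRHL2 list, with a q above 0.05, could be background windows that pass an unadjusted p. Its regions met MLL3 regions 1.94 times as often as with MLL3 moved by 10 to 50 kb, and 2.14 times outside the tracts, against 24.1 times for GRHL2 regions with a −log10 q of at least 100. These ratios fall on either side of the bound of 2 set for the test. In place, 1351 of the weak regions met an MLL3 region, against 697 ± 24.2 after moves (mean and SD over the moves). Outside the tracts 1250 did, against 584 ± 22.6. Background windows unrelated to MLL3 are thus argued against as the only source of the weak regions that met MLL3. Those made up only 1.28% of the weak regions, and for the others background and weak binding cannot be told apart. Open chromatin recovered by any antibody could give the same excess, and no biological explanation was tested.

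A further hypothesis was that MLL3-only regions lie next to GRHL2 regions. Of the 1823 such regions, 515 (28.3%, 95% interval 26.2 to 30.4%) had a GRHL2 region within 1 kb, against 13.5% ± 0.803 (SD of 1000 moves by 10 to 50 kb), a ratio of 2.09 (one-sided permutation of positions, p = 0.001, the smallest possible). The bound of 2 was set beforehand, but the range of the moves was chosen after the density of the lists had been seen. The ratio passed that bound by less than the spread of the moves, and within 5 kb it was 1.28.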
